A study of Mus musculus with 9 samples.

How the data were processed

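RNA was measured by bulk sequencing in 9 libraries from 4 cell populations of the mouse hair follicle, sorted by flow cytometry from back skin at postnatal day 30 with follicles in anagen VI, the last stage of hair growth. Per the labels, the sort used GFP, integrin α6, integrin β1, CD34, Sca-1 and P-cadherin, and RNA was taken up in TRIzol LS, purified with a Direct-zol kit, prepared with an Illumina TruSeq mRNA kit and sequenced as read pairs on HiSeq machines. The strain label names an Lhx2-GFP line on CD1, while the extraction text names K14-H2BGFP mice, so the source of the GFP signal is not settled. The sex label reads "Mixed" for every sample. How the gates were set, how many mice went into a sample, and whether replicates came from separate animals are not stated, so a p-value here measures the spread between these samples.

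The authors' per-sample tables give RSEM expected counts, that is, estimated read counts per gene that are not scaled for depth. The deposited tables also give transcript levels as TPM, scaled by the authors to the same sum in every library after division by effective length. The effective length of each gene, in bases, is the other deposited column used. Per the labels, Bowtie2 2.2.9 and RSEM 1.2.30 were run against mm10, and their parameters and the counting strand are not stated, so values of genes that overlap on opposite strands are uncertain. Effective length equalled length minus 50 in 99.85% of gene rows of each library, although the labels give read pairs. Each table holds 46517 gene rows, of which 98.9% have an identifier in GENCODE M21, the source of positions and gene types. The 92 rows of ERCC spike-in standards are at 0 in all 9 libraries. In each library the identifier, transcript list, length and FPKM columns gave no reported value, 9 FPKM columns in all. A deposited TPM table for the whole series was not used, because 3 of its column names are not the label of any sample.

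Expected counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr on the 4 populations, which left 20491 genes, and libraries were scaled by TMM, with factors from 0.9 to 1.127. All 9 libraries entered 1 quasi-likelihood fit of 4 population means with 5 residual degrees of freedom. Each comparison was a 2-sided F-test, with p-values adjusted by Benjamini and Hochberg over the genes tested and a threshold of 0.05. Standard errors of log2 fold changes are the size of the change divided by the square root of F. Levels are normalised CPM, that is, counts scaled to library size, with the SD over libraries. A gene was a signature gene of a population when the largest of its 3 one-sided p-values against the other populations, adjusted in the same way, was under 0.05. Where all libraries of a population were at 0, the fold is a lower bound from a floor of 3 counts per library, which covers counting error only. Floors and CPM rest on reads without molecular identifiers.

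Total expected counts were 29902799, 25098237 and 29739051 in the HFSC libraries, 64569201 and 88596741 in ORS, 60990600 and 63511683 in basal HB, and 50752545 and 45438637 in suprabasal HB. A floor of 3 counts is worth between 0.034 and 0.12 CPM. The procedure was tested on simulated counts with each gene's mean over the 9 libraries, its dispersion and the library sizes, in which 100 genes were raised 2-fold and 100 raised 4-fold in basal HB among 20491. It called 35% of the 2-fold and 70% of the 4-fold genes at the sizes of basal HB against ORS, and 39% and 76% at those of basal HB against HFSC. At the sizes of suprabasal HB against basal HB it called 35% and 68%. At most 0.05% of the unchanged genes were called. In the data 27.9% to 48.9% of genes were called in the 4 comparisons, far more than were changed in the simulation. The adjusted threshold is stricter where few genes change, so these simulated shares do not carry over to the data.

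The gene lists were written before the data were examined, as were the comparisons, tests and most alternatives. They cover bulge stem cell genes, outer root sheath and companion layer keratins, basement membrane and hemidesmosome, matrix transcription factors, inner root sheath, hair keratins, DNA replication, mitosis, CDK inhibitors, WNT targets, WNT ligands, secreted WNT antagonists, the hedgehog, BMP and TGF-beta, and NOTCH pathways, FGF and EGF family signals, ribosome biogenesis, glycolysis, oxidative phosphorylation, desmosome and adherens junction, epidermal differentiation, immediate early and heat shock genes, sebaceous gland, dermal fibroblast and dermal papilla, melanocyte, immune cell, endothelial and blood, and the sort markers. The 28 lists were tested in the 4 comparisons with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over all 112 tests. Lists can share genes, such as Cd34, Lhx2, Itga6, Itgb1, Vdr, Col17a1, Lgr5, Notum and Wif1, so their results are not independent. Camera compares a list with the other genes. Camera with an estimated correlation and fry, which asks whether a list moves one way on balance without a comparison to other genes, were run beside it. Camera with the preset correlation called 58 of the 112 tests, fry 70, and both 51. With an estimated correlation none of the 112 was called and the smallest adjusted p was 0.38. Counts of members that passed are given over all genes tested and adjusted over the list alone.

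Named genes follow a rule written in advance. For each comparison they are the 6 largest rises and 6 largest falls among genes past the threshold with at least 20 CPM in the higher population and no overlap of libraries, the 2 members with the smallest p of each list called by camera, and the sort markers. For each signature they are the 5 genes with the largest smallest fold over the other populations. Gene models without a given name were counted and not named. For the named pseudogenes and Yam1, the share of 25-base words of their transcripts held by another gene was measured after the values were seen. Sums of the genes counted in HFSC alone, or in the other 6 alone, with their copies were tried first and set aside, because a more abundant copy fixes such a sum, as was the change of the members without copies, which their choice fixes. The copies alone were compared with genes within 2-fold of their mean CPM instead. Members of a list could also be named where that list is described. A second ranking among protein-coding autosomal genes other than ribosomal protein genes was added after the first was seen.

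The alternatives were DESeq2 1.42.0 size factors, upper-quartile scaling, the DESeq2 Wald test, no low-count filter, a stricter filter of 5 CPM in 2 libraries, effective length as an offset, the replicate number as a block, only the populations compared, limma on log2 of the deposited TPM plus 1 or plus 0.1, a log2 fold change of at least 1, and each library left out in turn. Thinning all libraries to the depth of the shallowest and counting only protein-coding autosomal genes were added after the data were seen. Figures were drawn with matplotlib 3.10.9.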

Results

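Gene expression was measured by RNA sequencing in 9 libraries from 4 sorted populations of mouse back skin at postnatal day 30, in the growth phase of the hair cycle. Hair follicle stem cells (HFSC), which reside in the bulge of the follicle, gave 3 libraries. The outer root sheath (ORS), the basal cells of the hair bulb (basal HB) and its suprabasal cells (suprabasal HB) gave 2 libraries each. The ORS lines the follicle between bulge and bulb, and bulb cells divide and differentiate into the hair shaft and inner root sheath. Total counts per library ranged from 25098237 to 88596741, and the 3 HFSC libraries, at 25098237 to 29902799, were the shallowest. Genes of the mitochondrial genome took 4.36% of counts in both suprabasal HB libraries and 2.28% to 2.89% in the other 7. The series sets stem cells beside the sheath and the layers of the bulb.

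The 4 populations separated from one another in principal components of log2 CPM, of which the first 3 held 54.5%, 15.9% and 13.7% of the variance. Pearson correlations across genes were 0.973 to 0.991 between libraries of 1 population and 0.876 to 0.958 between populations, where genes are not independent replicates. The lowest correlations, 0.876 to 0.886, were those of suprabasal HB with HFSC. Libraries of the populations compared did not overlap for 61.8% of genes in ORS against HFSC and 69.7% in basal HB against HFSC, where chance gives 20%. In basal HB against ORS and in suprabasal HB against basal HB these shares were 67.4% and 68.5%, where chance gives 33.3%.

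**Figure D1:**
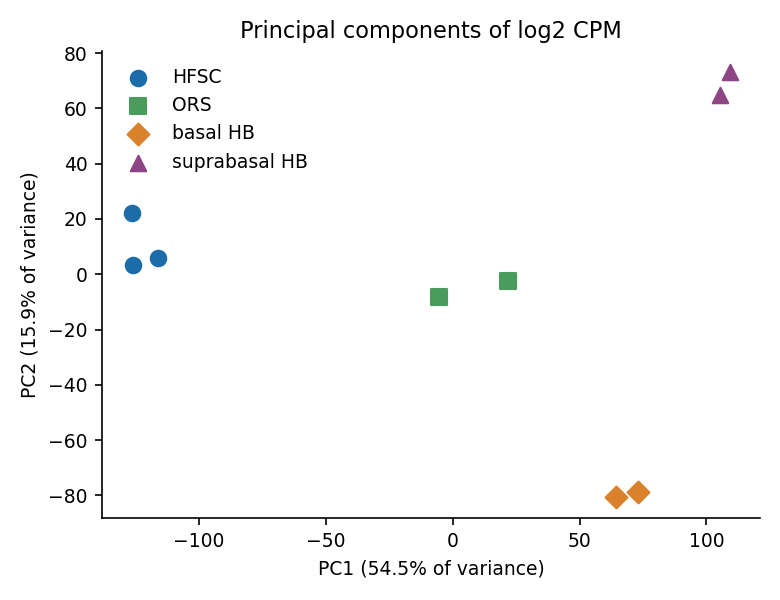
Principal components of log2 CPM in the 9 libraries, 1 point per library, coloured by population; the axes give component scores without a unit and the share of variance. The first component, with 54.5% of the variance, runs from the 3 HFSC libraries to the 2 suprabasal HB libraries.

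In ORS against HFSC, bulge stem cell genes, outer root sheath and companion layer keratins and basement membrane genes were lower, and genes of DNA replication and mitosis were higher. With an estimated correlation none of these lists was called (adjusted p of 0.44 to 0.47). Sox9, a transcription factor required by hair follicle stem cells (ENSMUSG00000000567, mm10 chromosome 11, 112782224 to 112787760), stood at 16.6 ± 1.28 CPM in ORS (SD, n = 2) and 137 ± 13.2 CPM in HFSC (n = 3), 8.24-fold lower. Cd34 encodes a surface protein used in the sort, so the gates may set its fall from 379 ± 33.7 to 73.2 ± 10.6 CPM. Aurkb, a kinase of chromosome segregation (ENSMUSG00000020897, chromosome 11, 69045647 to 69051664), rose from 35.8 ± 1.43 to 90.3 ± 2.95 CPM, and Chaf1a, which loads histones on new DNA, rose by 1.16 on the log2 scale. In edgeR, 3703 genes were higher and 4873 lower in ORS among 20491 tested, of which 1486 and 2283 differed by at least 2-fold.

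Of 18 bulge stem cell genes, 13 fell, 1 rose (Lhx2, 2.35-fold, adjusted p = 0.0055) and 4 did not pass, and 14 fell when adjusted over the list alone. Lgr5, a receptor of stem cells, was among those that did not pass, at 344 ± 111 CPM against 531 ± 18.2 (adjusted p = 0.076). Among 8 outer root sheath and companion layer keratins, 6 fell, also when adjusted over the list alone, with Krt14 lower by 5.78-fold and Krt17 by 4.40-fold. The basement membrane and hemidesmosome list, 27 genes of which Dst has 2 Ensembl entries, had 20 of 28 entries fall and none rise, again the same counts adjusted over the list alone. In it Col17a1, a hemidesmosome collagen, fell by 2.2 on the log2 scale (SE 0.21). Camera called these 3 lists down with adjusted p = 0.00017, 0.0032 and 1.7e-05, and adjusted p was 0.44 to 0.47 with an estimated correlation. The desmosome and adherens junction list had 12 of 19 fall (Pkp3, Jup), epidermal differentiation 9 of 16 (Sbsn, Spink5), immediate early and heat shock genes 15 of 24 (Ier3, Socs3) with 2 that rose, and FGF and EGF family signals 11 of 24 (Hbegf, Fgf18) with 1 that rose. Their adjusted p-values were 0.0032, 0.014, 0.003 and 0.02, and 0.47 to 0.59 with an estimated correlation. Adjusted over the list alone 13, 10, 17 and 12 fell and 1, 0, 2 and 1 rose. Without ORS replicate 2 the epidermal list had adjusted p = 0.0568 and the FGF and EGF list 0.0541. Marker genes of dermal fibroblasts and dermal papilla fell in 10 of 24 cases (Sparc by 3.25-fold, Dpt by 4.54-fold) and Dcn rose, and those of endothelium and blood fell in 6 of 15 (Tek by 2.86-fold, Hba-a1 by 4.94-fold), with 10 and 1 and with 5 and 0 adjusted over the list alone. Camera adjusted p was 0.0038 and 0.037, and 0.67 and 0.60 with an estimated correlation. By fry the dermal list had 0.0626. Without ORS replicate 2 the camera values were 0.135 and 0.129, and Hba-a1 had 0.0521; without HFSC replicate 3 the endothelial list had 0.089.

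All 32 genes of the mitosis list rose, with a median of 1.08 on the log2 scale, and 31 of 32 DNA replication genes rose with a median of 0.95. Both counts were unchanged when adjusted over the list alone. Ribosome biogenesis genes rose in 25 of 28 cases, 27 adjusted over the list alone, and included Mycn, a transcription factor of growth (5.30-fold), and Rrp12 (2.15-fold). Camera gave adjusted p = 5.5e-16, 8.7e-14 and 6.8e-10 for these lists, and 0.44 to 0.46 with an estimated correlation. Matrix transcription factors rose in 9 of 16 cases, among them Msx2, from 44.7 ± 6.49 to 167 ± 2.32 CPM, and Dlx3 (2.37-fold), and Vdr fell by 0.81 on the log2 scale. Adjusted over the list alone, 9 rose and 2 fell. Of 14 WNT targets 6 rose and none fell, and 9 rose and 1 fell adjusted over the list alone. Axin2 (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), a feedback inhibitor induced by WNT signals, reached 40.2 ± 8.90 CPM against 14.1 ± 1.88 in HFSC, and Znrf3, which removes WNT receptors, rose 2.65-fold. WNT ligands had 4 of 10 rise (Wnt4, Wnt5a, Wnt6, Wnt10b) and Wnt5b fall, also adjusted over the list alone. The adjusted p-values of the transcription factor, target and ligand lists were 0.0037, 0.0034 and 0.038, and 0.44 to 0.47 with an estimated correlation. The call of the ligand list was lost without any 1 of 5 libraries: adjusted p was 0.0757, 0.0826 and 0.0553 without HFSC replicate 1, 2 and 3, 0.106 without ORS replicate 1 and 0.054 without suprabasal HB replicate 2.

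The genes with the largest changes in this comparison had no counts, or almost none, in 1 of the populations. Rps12, a ribosomal protein gene, was at least 1983-fold higher and Eif2s3y, on the Y chromosome, at least 463-fold higher in ORS. The others were Ddx3y and Uty, also Y-linked, and the pseudogenes Rps26-ps1 and Rps15a-ps7. The largest falls included the RNA gene Yam1, which had 1068 ± 214 CPM in HFSC and 0 in ORS, at least 27440-fold lower, and the pseudogenes Rpl10-ps1, Rps15a-ps5, Rps2-ps6 and Rpl36a-ps3. These pseudogenes and Yam1 each share a fraction of 0.707 to 1 of their 25-base words with another gene, so their values are uncertain. Rps12 was at 0 in all 3 HFSC libraries and counted in the other 6, so whether its transcript is absent from HFSC is uncertain too. The 3 HFSC libraries had 0, 0 and 1 counts of Ddx3y and 1286, 1187 and 1437 CPM of Xist, the RNA of the inactive X chromosome. ORS replicate 1 had 93.0 CPM of Ddx3y and 1.11 CPM of Xist, and ORS replicate 2 had 51.7 and 1460. Among protein-coding autosomal genes, a ranking chosen after its values were seen, Atp5g2, Btg3, Glcci1, Adnp, Zbtb16 and Tspan18 rose most, by 6.05-fold to 13.6-fold. Atn1, Krt6a, Plekhb1, Anxa8, Sbsn and Scrg1 fell most, by 15.3-fold to 65.7-fold. The symbol Atn1 has several Ensembl entries, and its value is that of ENSMUSG00000107478 alone. This entry had a mean of 78.25 CPM in HFSC and at most 1.159 CPM in the other populations. How reads divide between the entries was not tested. Of the 6 sort markers, Lhx2 rose and Cd34, Itgb1, Itga6, Cdh3 and Ly6a fell, with camera adjusted p = 0.028, and 0.47 with an estimated correlation. The sort used the proteins of these genes other than Lhx2, so the gates may set their direction. Cd34 is also in the bulge stem cell list, and Itga6 and Itgb1 are in the basement membrane list. Lhx2 counts as a sort marker by the strain label alone. On deposited TPM, whose median log2 change lay higher by 0.3 with a pseudocount of 1 and by 0.33 with 0.1, limma called 5991 genes higher and 2756 lower, 68.5% higher against 43.2% by edgeR on counts, and 5982 and 2712 with 0.1. All 3 HFSC libraries differed from the other 6 in depth and in a set of genes counted in 1 side alone, and the Y-linked genes Ddx3y, Eif2s3y and Uty were at or near 0 in those 3 alone. Population, library preparation and the sex of the animals cannot be separated in comparisons with HFSC.

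**Figure D2:**
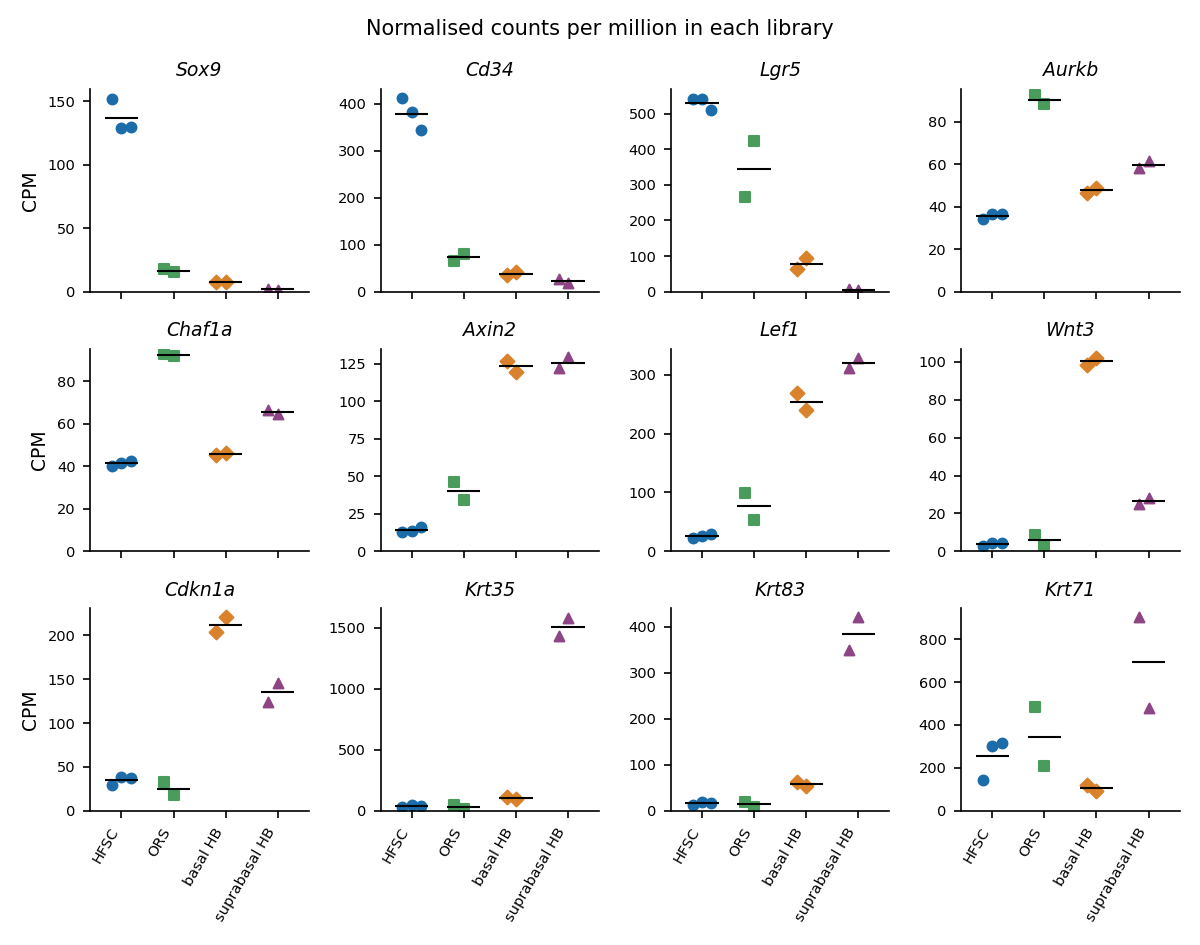
Normalised CPM of 12 genes on a linear axis from 0, 1 point per library and a line at the population mean, for HFSC (n = 3), ORS, basal HB and suprabasal HB (n = 2 each). Sox9 and Cd34 are highest in HFSC, Aurkb and Chaf1a in ORS, Wnt3 and Cdkn1a in basal HB, and the hair keratins Krt35 and Krt83 in suprabasal HB.

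In basal HB against ORS, the lists of DNA replication and mitosis were lower. The lists of WNT targets and ligands, secreted WNT antagonists, hair keratins, sebaceous gland, melanocyte and dermal genes were higher. All of these lists lost their call with an estimated correlation (adjusted p of 0.42 to 0.49). Dkk2, a secreted WNT antagonist (ENSMUSG00000028031, chromosome 3, 132085292 to 132180304), rose from 0.518 ± 0.232 to 44.9 ± 2.26 CPM (SD, n = 2 in each population), 84.9-fold. Wnt3, a WNT ligand (ENSMUSG00000000125, chromosome 11, 103774150 to 103817957), rose from 5.84 ± 3.77 to 100 ± 2.65 CPM. Soat1, which makes cholesterol esters, rose from 65.7 ± 12.5 to 1009 ± 7.33 CPM. In edgeR 3241 genes were higher and 3004 lower in basal HB, of which 2254 and 945 differed by at least 2-fold.

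All 32 DNA replication genes and all 32 mitosis genes fell, also when adjusted over the list alone, with medians of -1.02 and -0.84 on the log2 scale. Pola1, the catalytic subunit of a replicative polymerase, fell 2.24-fold and Anln, which builds the division furrow, 2.09-fold. Ribosome biogenesis genes fell in 18 of 28 cases, 21 adjusted over the list alone, with Tcof1 and Nop56 as examples. Of 18 bulge stem cell genes, 13 fell and 3 rose (Nfatc1, Foxc1 and Fgf18), the same counts adjusted over the list alone. Nfib, a transcription factor of bulge cells, fell 3.27-fold and Lhx2 fell 7.60-fold. Camera called these 4 lists down with adjusted p = 8.6e-17, 1.8e-14, 1.9e-06 and 0.002, and 0.44 to 0.47 with an estimated correlation.

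WNT targets rose in 8 of 14 cases and fell in 2 (Lgr5 and Ccnd1), with 9 and 2 adjusted over the list alone. Nkd1, which dampens WNT signals, rose from 5.87 ± 2.50 to 38.5 ± 0.121 CPM. Secreted WNT antagonists rose in 7 of 10 cases and none fell, also adjusted over the list alone, and included Notum (10.6-fold) and Wif1 (5.94-fold). Notum, Wif1 and Dkk4 are also in the WNT target list, so the results of these lists are not independent. Of the WNT ligands 5 of 10 rose, among them Wnt7b (5.09-fold), and adjusted over the list alone 5 rose and 1 fell. These 3 lists had camera adjusted p of 0.0031, 0.00056 and 0.019, and 0.44 to 0.47 with an estimated correlation. Without ORS replicate 2 the ligand list had adjusted p = 0.0982. The BMP and TGF-beta list had 12 of 25 rise and 5 fall, the same adjusted over the list alone. In it Bmp2 rose 12.9-fold and Smad7, an inhibitor within the pathway, by 1.95 on the log2 scale. Its camera adjusted p was 0.04, and 0.44 with an estimated correlation, and the call was lost without basal HB replicate 2 (0.055), HFSC replicate 2 (0.0559), HFSC replicate 3 (0.06), suprabasal HB replicate 1 (0.0501) or suprabasal HB replicate 2 (0.0636).

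Hair keratins rose in 8 of 12 cases and 1 fell (Krt32), the same adjusted over the list alone. Krt83, a keratin of the hair shaft, rose from 14.1 ± 8.21 to 58.5 ± 6.60 CPM and Krt84 from 0.231 ± 0.0902 to 0.948 ± 0.120. The sebaceous gland list had 9 of 15 rise and 1 fall (Mgst1), the same adjusted over the list alone. Among those that rose were Soat1 and Dgat2 (7.28-fold), an enzyme of triglyceride synthesis. Its members Awat2, Elovl3, Cidea and Plin5 stayed low, at 1.85, 0.83, 0.31 and 0.25 CPM in basal HB replicate 1. Glycolysis genes rose in 9 of 19 cases, 10 adjusted over the list alone, with Hk1 (2.67-fold) and Aldoc (4.63-fold), and Slc16a1, a lactate transporter, fell. Cell cycle inhibitors of the CDK inhibitor list, which camera did not call (adjusted p = 0.054, and 0.47 with an estimated correlation), rose in 4 of 7 cases and fell in 1 (Cdkn2c), also adjusted over the list alone. Camera called it without ORS replicate 1 (0.0345), without basal HB replicate 1 (0.0275) and with no low-count filter (0.0244), and fry called it (0.000918). In it Cdkn1a rose 8.38-fold and Cdkn2b went from 3.79 to 41.6 CPM. Immediate early and heat shock genes rose in 10 of 24 cases, among them Egr3 and Ier3, and 12 rose and 1 fell adjusted over the list alone. Camera called the hair keratin, sebaceous, glycolysis and immediate early lists up with adjusted p = 0.0039, 0.00027, 0.0011 and 0.0073, and 0.42 to 0.63 with an estimated correlation. By fry the immediate early list had 0.0818.

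Marker lists of other cell types moved with these groups. The melanocyte list had 12 of 13 genes rise, 13 adjusted over the list alone, from Mitf (1.17 on the log2 scale), the regulator of pigment cells, to Gpnmb, which reached 2947 ± 98.2 CPM against 110 ± 61.5. All 13 were higher in ORS replicate 1 than in ORS replicate 2. The dermal fibroblast and dermal papilla list had 15 of 24 rise and 1 fall (Dcn), 16 and 1 adjusted over the list alone, with Pdgfrb (11.2-fold) and Inhba (25.6-fold). Both lists had camera adjusted p = 6.8e-06, and 0.47 and 0.49 with an estimated correlation.

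The largest rises by the rule were Tm4sf4, Dkk2, Masp1, Coch, Col13a1 and Tchhl1, by 41.8-fold to 102-fold. The largest falls were Lhx2, Cps1, Lgr6, Prss35, Dsg1a and Fmo2, by 5.70-fold to 7.60-fold. Among these, Prss35 had adjusted p = 0.0612 without basal HB replicate 1, and Cps1 (adjusted p = 0.045) had 0.0705 without HFSC replicate 2, 0.0612 and 0.122 without ORS replicates 1 and 2, 0.229 and 0.127 without basal HB replicates 1 and 2, and 0.0563 and 0.0633 without suprabasal HB replicates 1 and 2. Cps1 also lost its call with upper-quartile scaling (0.0519) and on TPM (0.0866 and 0.0906). The sort used the proteins of the sort markers other than Lhx2, so the gates may set their direction. Of the other sort markers, Cd34 fell 1.92-fold (adjusted p = 0.0047), a call lost without basal HB replicate 1 (log2 change of -0.818). Cdh3 stood at 290 ± 16.2 CPM against 406 ± 75.4 (adjusted p = 0.045), and its call was lost without any single library (0.0501 to 0.285) other than ORS replicate 1 (0.0172) and with DESeq2 size factors (0.0557), upper-quartile scaling (0.07), a stricter filter (0.063), only the 2 populations compared (0.0725) and TPM (0.154 and 0.159). Itgb1, Itga6 and Ly6a did not pass, although Itga6 passed with upper-quartile scaling (0.0294), the DESeq2 Wald test (0.0196), a stricter filter (0.0297) and TPM (0.0373 and 0.0404), and without ORS replicate 2 (0.0327), and the change of Ly6a turned above 0 on TPM (0.021) and without ORS replicate 1 (0.417). Without basal HB replicate 1, edgeR called 2133 genes higher and 1351 lower, and it called 1861 lower without basal HB replicate 2 and 1962 lower without ORS replicate 2.

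In basal HB against HFSC, bulge stem cell and basement membrane genes were lower, and matrix transcription factors, hair keratins, WNT targets and ligands and CDK inhibitors were higher, lists that had adjusted p of 0.44 to 0.47 with an estimated correlation. Axin2 rose from 14.1 ± 1.88 CPM (SD, n = 3) to 123 ± 4.91 CPM (n = 2), 8.72-fold. Sox9 fell from 137 ± 13.2 to 7.46 ± 0.00908 CPM, 18.4-fold. Cdkn1c, an inhibitor of cyclin-dependent kinases (ENSMUSG00000037664, chromosome 7, 143458339 to 143461050), rose from 5.73 ± 0.639 to 53.5 ± 9.18 CPM. In edgeR 4681 genes were higher and 5345 lower in basal HB, of which 2927 and 2595 differed by at least 2-fold.

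Of 18 bulge stem cell genes 15 fell and none rose, and 15 fell and 1 rose adjusted over the list alone. The basement membrane and hemidesmosome list had 18 of 28 fall and 4 rise, 18 and 5 adjusted over the list alone, with Lamb1 lower by 3.55-fold. All 6 sort markers fell, also adjusted over the list alone. Among them Itga6, with adjusted p = 0.036 and a log2 change of -0.35, was the smallest change. Without single libraries its adjusted p was 0.285 (HFSC replicate 1), 0.186 (HFSC replicate 2), 0.131 (HFSC replicate 3), 0.207 (basal HB replicate 1), 0.0805 (basal HB replicate 2) and 0.154 (suprabasal HB replicate 2), and on TPM its change turned to 0.095. It also lost its call with DESeq2 size factors (0.0565), upper-quartile scaling (0.117), no low-count filter (0.148), a stricter one (0.0588) and a length offset (0.0616), and Itgb1 lost its call on TPM (0.0617 and 0.064). Camera called the 3 lists down with adjusted p = 6.8e-06, 0.0031 and 0.0032, and 0.44 to 0.47 with an estimated correlation. The sort used the proteins of the sort markers other than Lhx2, so the gates may set the result of that list.

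WNT targets rose in 12 of 14 cases, and Lgr5 and Ccnd1 fell, also adjusted over the list alone. Lef1, a transcription factor of the pathway, rose from 25.8 ± 3.54 to 254 ± 19.8 CPM. WNT ligands rose in 7 of 10 cases, with Wnt4 (6.88-fold) and Wnt5a (7.81-fold), and Wnt5b fell, also adjusted over the list alone. Of 7 inhibitors of cyclin-dependent kinases 5 rose, the same adjusted over the list alone, among them Cdkn1a (6.12-fold). Matrix transcription factors rose in 9 of 16 cases and fell in 4, with Msx2 (6.80-fold) and Msx1 (7.13-fold), and hair keratins rose in 9 of 12 with 1 that fell, with Krt81 and Krt86, both unchanged adjusted over the list alone. The BMP and TGF-beta list had 15 of 25 rise and 6 fall, also adjusted over the list alone, with Smad7 (5.90-fold) and Smad6 (a log2 change of 1.93). For these lists in order, camera gave adjusted p = 0.00019, 0.0035, 0.0038, 0.016, 0.01 and 0.014, and 0.44 to 0.47 with an estimated correlation. The matrix transcription factor list had adjusted p = 0.0513 without HFSC replicate 2 and 0.0524 without suprabasal HB replicate 2.

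Mitosis genes rose in 15 of 32 cases, also adjusted over the list alone, with Plk1 higher by 1.42-fold and Cenpf by 1.53-fold, although Cenpf had adjusted p = 0.671 with a length offset. DNA replication genes fell in 7 of 32 cases, 4 adjusted over the list alone, with a median of -0.1 that turned to 0.2 on TPM and 0.03 with upper-quartile scaling, which moved the median of all genes by 0.33 and 0.14. Ribosome biogenesis genes rose in 12 of 28 cases with 1 that fell, also adjusted over the list alone, with Mycn (4.62-fold) and Polr1b (0.83 on the log2 scale). Camera adjusted p was 0.01, 0.23 and 0.03, and 0.72, 0.84 and 0.70 with an estimated correlation, and ribosome biogenesis had 0.104 without basal HB replicate 2. By fry the mitosis and ribosome biogenesis lists had 0.087 and 0.0533. All 13 melanocyte genes rose, with Gpnmb (35.1-fold) and Kit (6.52-fold), and 8 of 15 sebaceous gland genes rose with 1 that fell, also adjusted over the list alone. Their adjusted p was 4.5e-05 and 0.003, and 0.48 and 0.44 with an estimated correlation.

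The largest rises were again Rps12 (at least 2224-fold), Eif2s3y (at least 617-fold), Ddx3y, Rps26-ps1 and Uty, with Tm4sf4 (116-fold). The value of Rps12 is uncertain here too, since it was at 0 in HFSC and counted in every other population. The largest falls included Yam1, Rpl10-ps1, Rpl30-ps9, Rps2-ps6 and Rpl36a-ps3, all at 0 in basal HB and uncertain, since each shares a fraction of 0.835 to 1 of its 25-base words with another gene. In the ranking of protein-coding autosomal genes chosen after its values were seen, Tm4sf4, Myog, Foxq1, B3gnt5, Btg3 and Nccrp1 rose 48.4-fold to 116-fold. Atn1, Krt6a, Barx2, Atp8a2, Sox9 and Ltbp2 fell 17.3-fold to 111-fold. The value of Atn1 is again that of the Ensembl entry ENSMUSG00000107478 alone. Without basal HB replicate 1, edgeR called 3110 genes higher and 3397 lower. On TPM, with the median shifted by 0.33 to 0.38, limma called 7940 genes higher and 3018 lower (72.5% higher against 46.7%), or 7839 and 2957 with a pseudocount of 0.1, and upper-quartile scaling, which shifted the median by 0.14, gave 5915 and 4418 (57.2%).

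**Figure D3:**
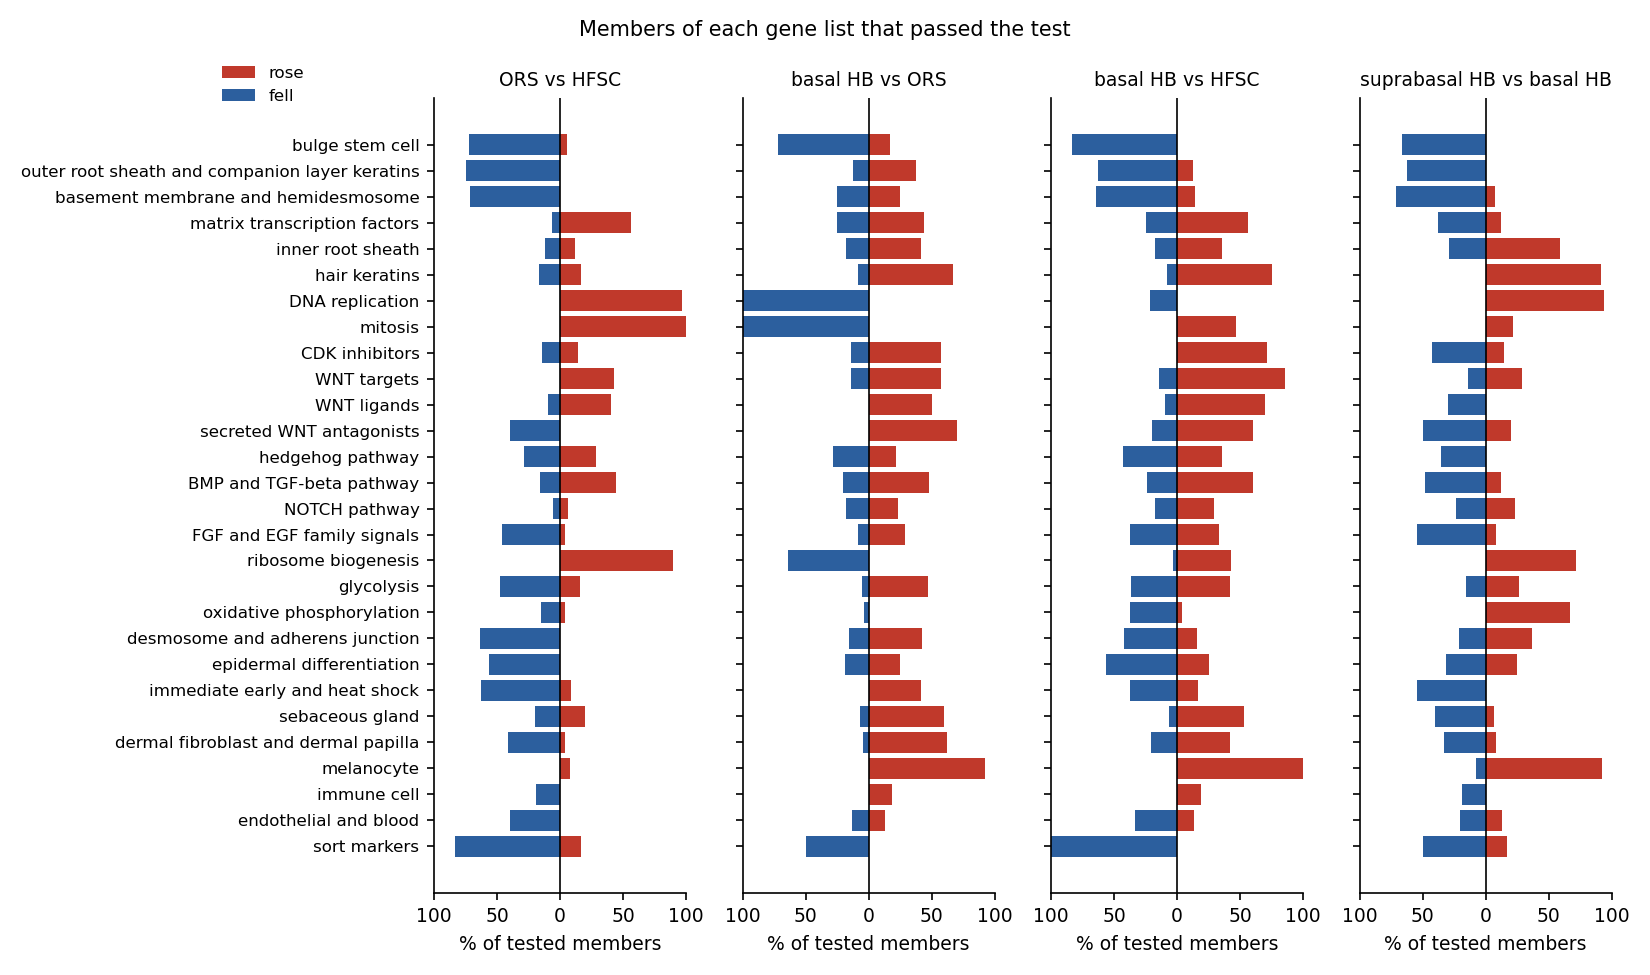
Members of the 28 gene lists that rose (right) or fell (left) in edgeR, as a percentage of the members tested, for the 4 comparisons. In the first panel 32 of 32 mitosis genes rose and in the next 32 of 32 fell; the median of the mitosis list in the last panel, where 7 of 32 rose, turns below 0 on TPM.

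In suprabasal HB against basal HB, hair keratins, pigment genes, DNA replication, ribosome biogenesis and oxidative phosphorylation were higher, and genes of the basement membrane, bulge stem cells, and FGF, EGF and BMP signals were lower. The call of each of these lists was lost with an estimated correlation (adjusted p of 0.38 to 0.49). Krt31, a hair shaft keratin (ENSMUSG00000048981, chromosome 11, 100046646 to 100050551), rose from 3.12 ± 0.139 to 24.97 ± 1.07 CPM (SD, n = 2 in each population), 8.01-fold. Krt35, which is made as shaft cells begin to harden, rose from 104 ± 15.5 to 1506 ± 106 CPM. Lgr5 fell from 78.5 ± 21.8 to 6.07 ± 1.97 CPM. In edgeR 2679 genes were higher and 3042 lower in suprabasal HB, of which 774 and 2047 differed by at least 2-fold.

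Hair keratins rose in 11 of 12 cases, all but Krt34 (adjusted p = 0.081), and in all 12 adjusted over the list alone. Camera adjusted p was 1.5e-08, and 0.38 with an estimated correlation. The inner root sheath list, which camera did not call (adjusted p = 0.29, and 0.76 with an estimated correlation), had 10 of 17 rise and 5 fall, 10 and 6 adjusted over the list alone. The keratins Krt25, Krt27, Krt28, Krt71, Krt72, Krt73 and Krt74 were among those that rose, and Tchh, Tchhl1, Padi3, Tgm3 and S100a3 fell. Tchh, a protein of the hardened sheath and medulla, went from 4005 ± 265 to 625 ± 4.23 CPM.

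DNA replication genes rose in 30 of 32 cases, 31 adjusted over the list alone, with a median of 0.69 on the log2 scale. Ccne1, a cyclin that starts replication, rose 1.98-fold and Rfc3, a subunit of the clamp loader, 1.66-fold. Ribosome biogenesis genes rose in 20 of 28 cases, 25 adjusted over the list alone, with Rrp9 and Bop1, and oxidative phosphorylation genes in 18 of 27, 26 adjusted over the list alone, with Cox6a1 and Cyc1. Cyc1 had adjusted p = 0.0624 without basal HB replicate 1, and 0.0701 and 0.0761 on TPM. Genes of the mitochondrial genome took 4.36% of counts in both suprabasal HB libraries and 2.6% and 2.89% in basal HB. These 3 lists had camera adjusted p = 2.1e-12, 1.4e-07 and 1.3e-07, and 0.44 to 0.48 with an estimated correlation. Mitosis genes rose in 7 of 32 cases, also adjusted over the list alone, with a median of 0.21 that turned to -0.05 on TPM, which moved the median of all genes by -0.25, and included Nuf2 (1.47-fold) and Aurkb (1.25-fold). The mitosis list had camera adjusted p = 0.0031, and 0.67 with an estimated correlation, and 0.0577 without suprabasal HB replicate 2 and 0.149 by fry. Nuf2 had adjusted p = 0.0626 without basal HB replicate 1, and 0.0925 and 0.0957 on TPM. Aurkb had 0.126 and 0.0636 without basal HB replicates 1 and 2 and 0.115 without suprabasal HB replicate 2, 0.0521 with no low-count filter, and 0.735 and 0.745 on TPM, where its log2 change was 0.061 and 0.062.

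The basement membrane and hemidesmosome list had 20 of 28 fall and 2 rise, 22 and 2 adjusted over the list alone, with Lamb3 (5.88-fold lower). Bulge stem cell genes fell in 12 of 18 cases, 13 adjusted over the list alone, with Gas1 beside Lgr5, and outer root sheath and companion layer keratins fell in 5 of 8, also adjusted over the list alone, with Krt75 and Krt17. Immediate early and heat shock genes fell in 13 of 24 cases, 15 adjusted over the list alone, with Socs3 and Hspb1. The BMP and TGF-beta list had 12 of 25 fall and 3 rise, 14 and 3 adjusted over the list alone, with Smad7 and Bmp6, and FGF and EGF family signals had 13 of 24 fall and 2 rise, 13 and 4 adjusted over the list alone, with Fgfr1 and Hbegf. Camera adjusted p was 2e-07, 1.1e-05, 0.014, 1.1e-05, 0.0037 and 0.036 for these 6 lists, and 0.44 to 0.49 with an estimated correlation. The FGF and EGF list had adjusted p = 0.141 without suprabasal HB replicate 2, 0.0553 without basal HB replicate 2 and 0.0586 without HFSC replicate 2.

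The melanocyte list had 12 of 13 genes rise and Gpnmb fall, also adjusted over the list alone, with camera adjusted p = 7.7e-06, and 0.47 with an estimated correlation. Dct, an enzyme of melanin synthesis, was at 5205 and 5491 CPM in the suprabasal HB libraries and 489 and 348 CPM in the basal HB libraries. Mitf rose 8.44-fold and Ednrb 9.23-fold. Of the largest rises by the rule, Pmel, Tyrp1, Oca2 and Slc45a2 are pigment genes, and B3galt5 and Npy were the others, all between 15.5-fold and 16.8-fold. Pmel had adjusted p = 0.0602 without basal HB replicate 2, and Tyrp1 had 0.0664 and 0.087 without basal HB replicates 1 and 2. The dermal list had 8 of 24 fall and 2 rise, 10 and 2 adjusted over the list alone, with Pdgfrb (14.2-fold) and Acta2 (19.9-fold). The sebaceous gland list had 6 of 15 fall and 1 rise, 6 and 2 adjusted over the list alone, with Soat1 (9.78-fold) and Plin2, and 3 of 16 immune cell genes fell, also adjusted over the list alone, with Cd74 and H2-Aa. Camera adjusted p was 0.024, 0.047 and 0.045, and 0.71, 0.44 and 0.63 with an estimated correlation. Single libraries ended these calls. The dermal list had adjusted p = 0.338 without suprabasal HB replicate 2, 0.0776 without basal HB replicate 1 and 0.0509 without HFSC replicate 1. The immune list had 0.287 without suprabasal HB replicate 1, 0.0878 and 0.0542 without basal HB replicates 1 and 2, and 0.0575 and 0.0513 without HFSC replicates 1 and 2. The sebaceous list kept its call only without HFSC replicate 1 or basal HB replicate 2, with 0.0531 to 0.0776 otherwise. With DESeq2 size factors the sebaceous and immune lists had 0.0544 and 0.0587, and by fry the dermal and immune lists had 0.0874 and 0.118. H2-Aa had adjusted p = 0.0562 without basal HB replicate 2.

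**Figure D4:**
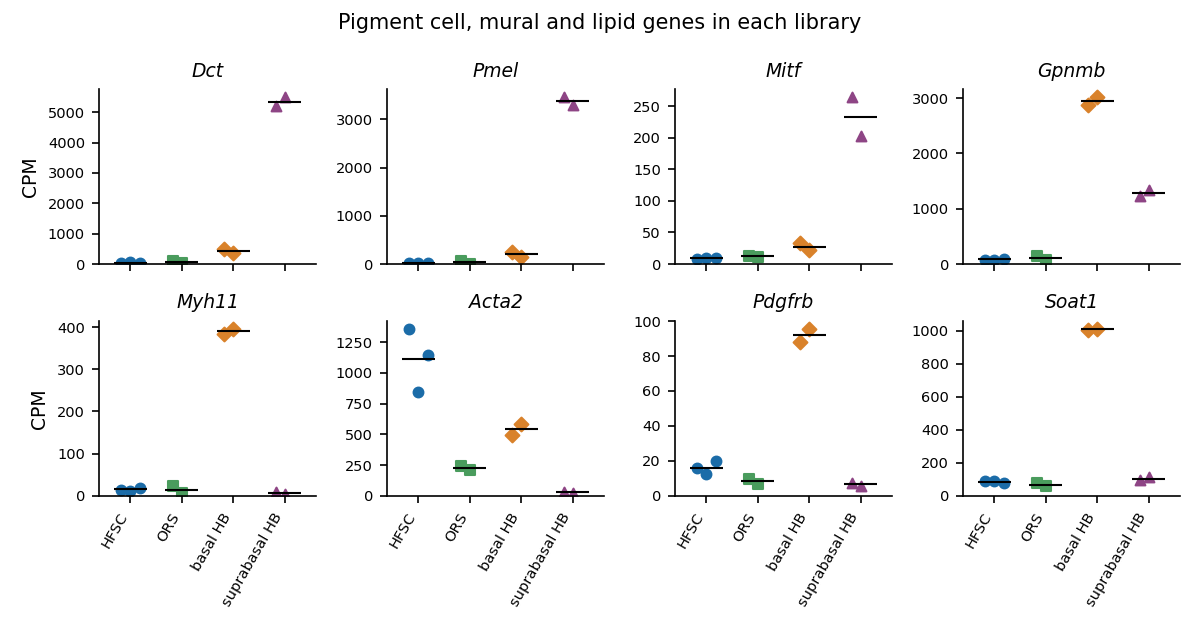
Normalised CPM of 8 genes on a linear axis from 0, 1 point per library and a line at the population mean, for HFSC (n = 3), ORS, basal HB and suprabasal HB (n = 2 each). Dct, Pmel and Mitf are highest in suprabasal HB, Gpnmb, Myh11, Pdgfrb and Soat1 in basal HB, and Acta2 in HFSC.

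The largest falls by the rule were Rps24-ps3, Xist, Olfr558, Tm4sf4, Olfr78 and Myog. Rps24-ps3 was at 0 in suprabasal HB, at least 939-fold lower, and is uncertain, since this pseudogene shares a fraction of 0.754 of its 25-base words with another gene. Xist had 359 and 298 CPM in the basal HB libraries and 1.22 and 1.05 CPM in the suprabasal HB libraries (adjusted p = 0.031), and its call was lost without any basal HB or suprabasal HB library (0.0685 to 0.15) and without HFSC replicate 3 (0.0517), and on TPM plus 1 (0.0595). Ddx3y stood at 70.27 and 71.19 CPM in basal HB and at 85.63 and 96.17 CPM in suprabasal HB, so that Xist and Ddx3y were both above 50 CPM in basal HB but not in suprabasal HB, and the sex of the animals is not separated from population here either. Rps24-ps3 (adjusted p = 0.03) had 0.0512 to 0.11 without any single library other than ORS replicates 1 and 2. In the ranking of protein-coding autosomal genes chosen after its values were seen, Dkk2 and Rcan2 joined the falls, by 85.3-fold and 56.2-fold. The sort used the proteins of the sort markers other than Lhx2, so the gates may set their direction here too. Of these markers, Itgb1 fell 1.80-fold and Itga6 1.84-fold, and both are also in the basement membrane list. Cd34 fell 1.71-fold (adjusted p = 0.015), with adjusted p = 0.0955 without basal HB replicate 2 and 0.0602 without suprabasal HB replicate 2. Ly6a rose 2.35-fold (adjusted p = 0.039), a call lost without any basal HB or suprabasal HB library (0.0772 to 0.176) and without HFSC replicate 1 (0.0677), with upper-quartile scaling (0.0572) and on TPM (0.13 and 0.126). Cdh3 (340 ± 32 against 290 ± 16.2 CPM) and Lhx2 (356 ± 170 against 417 ± 88.8 CPM) did not pass. Without suprabasal HB replicate 1 Lhx2 was lower with adjusted p = 0.028, its change turned above 0 without suprabasal HB replicate 2 (0.162) or basal HB replicate 2 (0.005), and that of Cdh3 turned on TPM (-0.04). Without basal HB replicate 1, edgeR called 873 genes higher and 1888 lower, without basal HB replicate 2 it called 1295 and 1843, and without suprabasal HB replicate 2 it called 1411 higher. On TPM, with the median shifted by -0.25 to -0.27, limma called 1098 genes higher and 4269 lower (20.5% higher against 46.8%), or 999 and 4173 with a pseudocount of 0.1.

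Signature genes were higher in 1 population than in each of the 3 others, and their number was 2558 in HFSC, 111 in ORS, 761 in basal HB and 561 in suprabasal HB. Among protein-coding autosomal genes the numbers were 2087, 101, 704 and 508. Population, library preparation and the sex of the animals cannot be separated in the HFSC numbers, and HFSC had 3 libraries where the others had 2. On TPM plus 1 the HFSC, ORS and basal HB signatures held 1253, 237 and 1397 genes, so that basal HB had the most, and on TPM plus 0.1 the HFSC, ORS and suprabasal HB signatures held 1117, 187 and 263. In basal HB the leading genes were Tm4sf4, Dkk2, the olfactory receptor genes Olfr558 and Olfr78, and Myh11. Myh11, a myosin of smooth muscle, stood at 390 ± 7.61 CPM against at most 15.2 CPM elsewhere. The leading genes of suprabasal HB were B3galt5, the pigment genes Pmel, Tyrp1 and Oca2, and Npy. Their log2 changes were 4.01 to 4.07 over the next population. Which cells carry Myh11 and the pigment genes is not settled, as considered below. Lgr6, a receptor related to Lgr5, led the ORS genes at 169 ± 58.1 CPM against at most 40.4 CPM elsewhere, followed by Mycl, Galnt2, H19 and Sox5. In HFSC the leading genes included Yam1 and the pseudogenes Rpl10-ps1, Rpl36a-ps3 and Scp2-ps2, which share a fraction of 0.86 to 1 of their 25-base words with another gene, and the protein-coding genes, chosen after their values were seen, included Atn1, Krt6a, Scrg1 and Atp8a2. For Atn1 this holds for the Ensembl entry ENSMUSG00000107478 alone.

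The ORS signature rested on single libraries: it held 0 genes in edgeR without ORS replicate 2, without basal HB replicate 1 or without basal HB replicate 2, 69 and 45 without HFSC replicates 2 and 3, 26 without ORS replicate 1, and 16 and 11 without suprabasal HB replicates 1 and 2. It held 350 genes by the DESeq2 Wald test, 66 with a length offset and 20 where a log2 change of at least 1 was asked for, a rule that left 1171 genes in HFSC and 364 in suprabasal HB. All 5 of its named genes lost their call without ORS replicate 2 and without either basal HB library (0.0699 to 0.106), Mycl also without suprabasal HB replicate 1 (0.0992) or 2 (0.0681), and H19 without ORS replicate 1 (0.0516). The suprabasal HB signature fell to 230 and 197 genes without basal HB replicates 1 and 2 and to 304 and 343 without suprabasal HB replicates 1 and 2. All 5 genes named for it lost their signature call without basal HB replicate 2 (adjusted p of 0.0676 to 0.264), and Pmel, Tyrp1 and Oca2 also without basal HB replicate 1 (0.102 to 0.198). Pmel had 0.0639 and 0.0656 without suprabasal HB replicates 1 and 2. Tyrp1 lost its signature call without any HFSC (0.0597 to 0.0771) or suprabasal HB library (0.0932 and 0.108), and on TPM plus 0.1 (0.076). The basal HB signature held 363 and 337 genes without basal HB replicates 1 and 2, and the HFSC signature 1559 and 1611 without HFSC replicates 1 and 3.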

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

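All 12 counts of genes (the genes higher and lower in 4 comparisons and 4 signatures) stayed within 1.5 times under size factors of DESeq2, upper-quartile scaling, no low-count filter and a stricter one, and 8 of 8 did with only the 2 populations compared. The DESeq2 Wald test moved 1 count, the ORS signature, to 350, and the effective-length offset moved it to 66. With a replicate block the ORS signature held 1 gene, the other 11 counts stayed within 1.5 times, and 10 named gene results lost their call. By edgeR adjusted p these were Cdh3 in basal HB against ORS (0.091), and Xist (0.0705) and Rps24-ps3 (0.0672) in suprabasal HB against basal HB. In the signatures they were Pmel (0.0563) and Tyrp1 (0.0996) of suprabasal HB, and Lgr6, Galnt2, H19, Sox5 and Tmtc1 of ORS (0.0585 to 0.0782). The block also ended the calls of the endothelial list in ORS against HFSC (0.0523), the BMP and TGF-beta list in basal HB against ORS (0.0553) and the sebaceous list in suprabasal HB against basal HB (0.0523), and gained that of the immune list in basal HB against ORS (0.038). Whether the replicate numbers pair samples is not stated. Differences between replicates 1 and 2 correlated between populations at -0.069 to 0.121, which cannot settle it. Protein-coding autosomal genes alone and thinning to the shallowest library were chosen after seeing the data, and both kept all 12 counts; after thinning all 228 named gene results kept their direction and side of the threshold.

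Under limma on log2(TPM + 1), ORS against HFSC had 5991 genes higher and 2756 lower, basal HB against HFSC 7940 and 3018, and suprabasal HB against basal HB 1098 higher. The signatures of HFSC, ORS and basal HB held 1253, 237 and 1397 genes. With a pseudocount of 0.1 these were 5982 and 2712, 7839 and 2957, and 999 higher, and the signatures of HFSC, ORS and suprabasal HB held 1117, 187 and 263. Asking for a log2 change of at least 1 gave 1486 higher and 2283 lower in ORS against HFSC, 945 lower in basal HB against ORS, 2927 and 2595 in basal HB against HFSC, 774 higher in suprabasal HB against basal HB, and signatures of 1171 (HFSC), 20 (ORS) and 364 (suprabasal HB), since this rule keeps fewer genes. On TPM the changes of Ly6a in basal HB against ORS (0.021 and 0.027), Itga6 in basal HB against HFSC (0.095 and 0.096) and Cdh3 in suprabasal HB against basal HB (-0.04 and -0.04) turned. Apart from the rule on the log2 change, the cause was not tested.

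With single libraries left out, ORS against HFSC had 2829 to 4389 genes higher and 3585 to 4897 lower, basal HB against ORS 2133 to 3538 and 1351 to 2994, basal HB against HFSC 3110 to 5790 and 3397 to 5358, and suprabasal HB against basal HB 873 to 2720 and 1843 to 3377. Signatures held 1559 to 2329 genes (HFSC), 0 to 80 (ORS), 337 to 810 (basal HB) and 197 to 599 (suprabasal HB). Ly6a in basal HB against ORS went from -0.448 to 0.417 and Lhx2 in suprabasal HB against basal HB from -0.828 to 0.162 on the log2 scale. The melanocyte list in ORS against HFSC turned without ORS replicate 1 (adjusted p = 0.0444, from 3.05e-05 to 0.593 over the libraries). Among named genes 1957 of these results stayed the same, 90 lost and 2 gained their call, and among list tests 956 stayed, 38 lost and 13 gained it. A library left alone in its population is assumed to vary like the other populations. Fewer samples and 4 residual degrees of freedom go with these losses, and the cause was not tested further.

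Camera with an estimated correlation lost all 58 list calls, while fry lost 7 and gained 19. The HFSC libraries are the shallowest, so a gene at 0 there is known only to lie under about 0.1 to 0.12 CPM, against 0.034 to 0.066 CPM in the other 6.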

Other observations

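Signalling lists that camera did not call still held genes with large changes. In the hedgehog list Hhip, which binds the ligand, rose 27.5-fold in basal HB against ORS, while Gli1 (2.61-fold) and Ptch1 (2.40-fold) fell. Of its 14 genes, 4 rose and 4 fell in ORS against HFSC, 3 and 4 in basal HB against ORS, 5 and 6 in basal HB against HFSC, and 0 and 5 in suprabasal HB against basal HB, with camera adjusted p of 0.70, 0.88, 0.93 and 0.088, the last of which fry called (0.00882). In the NOTCH list Notch3 rose 6.86-fold in basal HB against ORS and Notch1 rose 3.22-fold in suprabasal HB against basal HB. Notch3 is also among the smooth muscle genes considered below, whose source is not settled. Of 17 NOTCH genes 1, 4, 5 and 4 rose and 1, 3, 3 and 4 fell in the 4 comparisons, with adjusted p of 0.92, 0.28, 0.40 and 0.79, and fry called both comparisons of basal HB with ORS and HFSC (0.0355 and 0.048). Secreted WNT antagonists fell in 4 of 10 cases in ORS against HFSC, where Sfrp1 was 11-fold lower, and 6 rose and 2 fell in basal HB against HFSC, with adjusted p of 0.12 and 0.21. The first of these was called without ORS replicate 1 (0.011) and by fry (0.0068). In suprabasal HB against basal HB Sfrp4 rose 13-fold, Dkk2 fell 85.3-fold, and 2 rose and 5 fell (adjusted p = 0.24).

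Glycolysis genes rose in 3 and fell in 9 of 19 cases in ORS against HFSC (adjusted p = 0.091), a list called with no low-count filter (0.0316) and by fry (0.00157). Oxidative phosphorylation genes fell in 10 of 27 cases and 1 rose in basal HB against HFSC, with adjusted p = 0.05 and a median of -0.28 that turned to 0.05 on TPM, which moved the median of all genes by 0.33. Camera called it without basal HB replicate 2 (0.0148), without ORS replicate 1 (0.0488) and with no low-count filter (0.0497). Inner root sheath genes rose in 7 of 17 cases and 3 fell in basal HB against ORS (adjusted p = 0.12, but 0.0148 without ORS replicate 1 and 0.0159 by fry), where Tchh went from 120 to 4005 CPM. Among desmosome and adherens junction genes 8 of 19 rose and 3 fell in basal HB against ORS (0.14, and 0.0254 by fry), and among epidermal differentiation genes 4 of 16 rose and 3 fell (0.40), Ivl by 12-fold. Immune cell genes rose in 3 of 16 cases in basal HB against ORS (0.064, but 0.0225 without ORS replicate 1 and 0.0482 without suprabasal HB replicate 1) and endothelial and blood genes in 2 of 15, with 2 that fell (0.29). Suprabasal HB against HFSC had 5172 genes higher and 5390 lower, and against ORS 2927 higher and 3094 lower.

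All 6 tests in the paragraphs that follow were chosen only after the result was seen.

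A set of 24 genes was counted in all 3 HFSC libraries and at 0 in the other 6 (15 genes) or the reverse (9), and 62.5% of it are pseudogenes against 5.6% of genes tested. Reads shared with near-identical copies could give this, in which case the copies should change the opposite way: they did so for 10 of the 19 members that have copies, against 8.6 expected from other genes of like level (exact Poisson binomial test with members taken as independent, p = 0.33), which does not decide. For the 5 members with no copy by this rule this was not tested. Among them Rps12 had a largest share of 0.218, so shared reads are not excluded for it. Eif2s3y is Y-linked like Ddx3y and Uty, which were also at or near 0 in HFSC. A strain, library batch or alignment difference between the HFSC libraries and the other 6 could do the same, and no other division of whole populations held more than 2 such genes, so population and batch cannot be told apart here. Sex of the animals alone is argued against for the 15 genes counted in HFSC, since 3 of the other 6 libraries had Xist above 10% of its HFSC mean, at 298 to 1460 CPM, and none of these genes, and for the 9 others it stays open, untested.

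Melanocyte genes were higher in suprabasal HB than in basal HB, with Dct at 5352 against 419 CPM, the most abundant of the list in suprabasal HB, as Gpnmb was in basal HB at 2947 CPM, and none of the 13 genes is in another list. Melanocytes in the sorted fraction may carry them. Of 13 melanocyte genes, 12 went the same way between the 2 basal HB libraries, and Gpnmb was the exception. A varying share of such cells would give this, but so would genes that are regulated together, so the test cannot decide. Between the 2 suprabasal HB libraries 8 were lower and 5 higher in replicate 1, by -0.18 to 0.39 on the log2 scale. A gate on a GFP made in keratinocytes alone, or against Kit protein, would remove such cells; the labels name GFP but not which line or how its gate was set. No biological explanation was tested.

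Contractile and mural genes such as Myh11, Pln and Des were highest in basal HB, whereas Acta2, Tagln, Smtn, Myl9, Tpm1, Tpm2, Cald1, Cspg4, Pdlim7, Flna and Mcam were highest in HFSC. Dermal fibroblasts in the sorted fraction could bring them, and Col1a1, Col1a2 and Col3a1 had a median log2 change of 0.56 in basal HB against ORS, which does not decide. These collagens do not stand for the whole dermal fibroblast and dermal papilla list, in which 15 of 24 genes rose and 1 fell. In it Corin was at 85.58 and 78.03 CPM in basal HB and at 6.97 and 2.42 CPM in ORS. Smooth muscle or mural cells in the sorted fraction could also bring the contractile and mural genes. Of 24 smooth muscle genes 14 rose and 4 fell, but among the 13 whose values had not been seen only 5 rose and 4 fell. Neither test settles the source, and a gate on a GFP made in keratinocytes alone or against PDGFRB protein would remove mural cells. No biological explanation was tested.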
